A study of Phanerodontia chrysosporium with 8 samples.

How the data were processed

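RNA-seq libraries of polyadenylated RNA from Phanerodontia chrysosporium RP-78 were analysed from processed files. Per the labels' protocols, the fungus grew on cellophane over malt and yeast agar in darkness at 37 °C over 7 days and was then moved to a moist chamber in dim light at 25 °C to fruit. Libraries were made from RNA of high integrity with an Illumina TruSeq RNA v2 kit, which does not mark strand, so reads of overlapping antisense models cannot be told apart. Stage, replicate number and flowcell were taken from the labels. The stages were vegetative mycelium (n = 3), young fruiting body (n = 2) and fruiting body (n = 3).

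The deposited per-sample files give, per the file headers, counts of unique and of total gene reads for 13602 gene models, with the length of each model. Their RPKM column is 0 for every model and was not used. The models carry JGI identifiers of this species, and 63.9% of their lengths are divisible by 3. A deposited matrix of the whole series holds log2 values for 12746 of these models, all 8 columns matching a sample by title. Its values follow log2 of total reads per length up to a constant for each library, with 99% of models of at least 100 reads within 0.00608, so they were read as log2 RPKM made by the authors before deposit. The submitters' processing notes name R 3.0.2, edgeR 3.4.2 and limma 3.18.13 without their role. The aligner, its settings and the genome release were not given in the sources used here.

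Uniquely mapped reads were used as counts, as deposited. They ranged from 16144543 to 35837246 per library, and 0.447 to 0.638% of gene reads in a library were not unique. The 10 most abundant models took 4.95 to 13.7% of unique reads. A count of 0 allows up to 3 reads, which is 0.0837 to 0.186 CPM. Such limits and the exact intervals of ratios (95%, Clopper-Pearson) cover counting error only, since reads carry no molecular identifiers. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 69.2 to 322), so no library was treated as a second deposit of another. This does not show that the libraries came from separate cultures.

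Tests were run in R 4.3.3. The main test was edgeR 4.0.16 (filterByExpr by stage, TMM factors, robust dispersions, robust quasi-likelihood fit and test) with all 8 libraries in 1 fit and stage as the only term, so that the stages share an estimate of the spread. It tested 12510 models in each of 3 contrasts and across the 3 stages together, and models with a Benjamini-Hochberg adjusted p below 0.05 are described as called. The SE of a log2 fold change was its absolute value divided by the square root of F. RPKM values in the text were computed from unique reads, model length and TMM-scaled library size. Principal components and correlations used log2 CPM with a prior count of 2. A called model was counted as going from near silence to abundance where every library of the lower stage was below 1 RPKM and every library of the higher stage at or above 10.

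Named models were chosen by a rule fixed before the data were examined. Per contrast, these were the 2 largest rises and 2 largest falls among called models with at least a 4-fold change, no overlap between the libraries of the stages, and a mean of at least 10 RPKM in the higher stage. Ratios of counts used library sizes multiplied by their TMM factors. For fruiting body against young fruiting body the rule had no member with all libraries and was applied without fruiting body replicate 3. Between mycelium and young fruiting bodies 529 models passed it upwards and 474 downwards. At most 0.0691% of the reads of any named model were not unique. The 26 gene lists fixed beforehand need product names or protein sequences, which the files do not pair with the IDs, so no list was tested and none is reported.

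The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), upper-quartile factors, no filter on low counts, a filter at 1 RPKM, total gene reads, the replicate number as a block, the flowcell as a covariate, the flowcell with all stages alone, only the 2 stages compared, and each library left out in turn. Chosen after seeing the data were limma-trend on the deposited log2 RPKM, the named-model rule without fruiting body replicate 3, and several settings for the models that peak in young fruiting bodies. Overlap between comparisons that share libraries was set beside 20 simulations of unchanged stages with the fitted dispersions.

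The fit was tested on simulated data with 100 models changed 2-fold and 100 changed 4-fold in each contrast. Before these changes each model had 1 mean over all stages, and its dispersion came from the fit of all 8 libraries. For young fruiting body against mycelium the fit recovered 4% and 55% of the changed models, with 5 false calls among 64. For fruiting body against young fruiting body it recovered 2% and 54%, with 5 among 61. For fruiting body against mycelium it recovered 7% and 73%, with 6 among 86. Without fruiting body replicate 3 it recovered 16% and 92% between fruiting body and young fruiting body, with 15 false calls among 123. No changed model was called in the wrong direction. Few models changed in these simulations, so a call needed a smaller unadjusted p than in a comparison with many calls. The recovery of 2-fold changes therefore does not carry over to the comparisons with mycelium. Among models called there, the median absolute log2 fold change was 1.54 in young fruiting bodies and 1.31 in fruiting bodies.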

Results

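Messenger RNA of the white-rot basidiomycete Phanerodontia chrysosporium, strain RP-78, was sequenced at 3 stages of fruiting, in 8 libraries. The vegetative mycelium (n = 3) is the growing hyphal mat. The young fruiting body (n = 2) was collected as initials, a dense mat with a clear edge against the mycelium around it. The fruiting body (n = 3) was collected once spore release had begun. The series describes the libraries of a stage as biological replicates, and without more detail on separate cultures the p-values measure the spread between these samples. Uniquely mapped reads on gene models came to 17018503, 35837246 and 20071680 in mycelium replicates 1, 2 and 3. They came to 26891371 and 22065312 in the young fruiting bodies and to 17573655, 24580228 and 16144543 in fruiting body replicates 1, 2 and 3. Each library of a stage reached at least 1 RPKM (reads scaled to model length and library size) in 11909 models in mycelium, 11911 in young fruiting bodies and 11587 in fruiting bodies.

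The first principal component of log2 CPM (counts scaled to library size) held 71.6% of the variance and parted mycelium from the fruiting libraries, but not young fruiting bodies from fruiting bodies. Mycelium lay at one end and the young fruiting bodies, with fruiting body replicates 1 and 2, at the other. Fruiting body replicate 3 stood apart from its stage. Across genes, which are not independent replicates, it correlated with fruiting body replicates 1 and 2 at r = 0.898 to 0.918, whereas those correlated with each other at 0.983. Its correlation with mycelium (0.863 to 0.871) lay above that of replicates 1 and 2 with mycelium (0.788 to 0.836). With the young fruiting bodies it correlated at 0.903 to 0.911, within its range with its own stage and above its values with mycelium. Fruiting body replicates 1 and 3 were run on a flowcell that held no other library, and replicate 2 shared a flowcell with all mycelium and young fruiting body libraries.

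**Figure D1:**
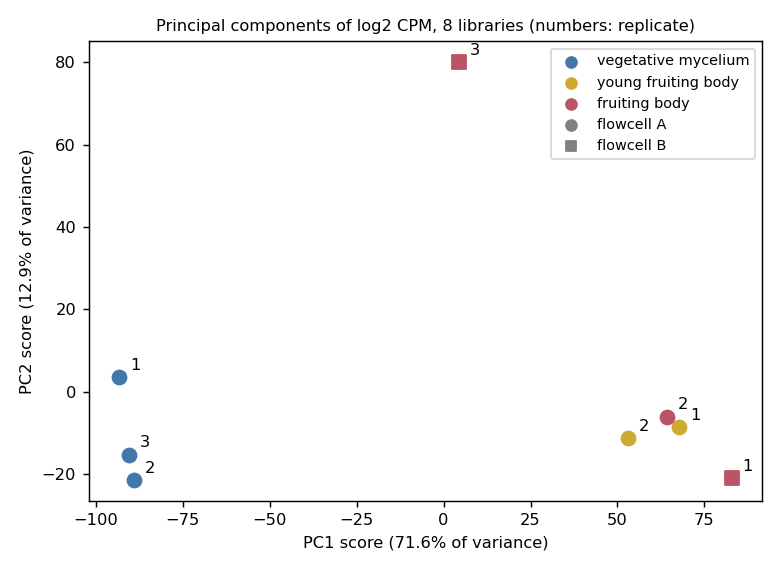
Scores of the 8 libraries on principal components 1 (71.6% of variance) and 2 (12.9%) of log2 CPM, with 1 point per library, colour for stage, symbol for flowcell and the replicate number beside each point. Fruiting body replicate 3, at 80.0 on the second axis, lies away from fruiting body replicates 1 and 2, and replicate 1 of the same flowcell does not.

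The start of fruiting was addressed by comparing young fruiting bodies with vegetative mycelium. To fruit, the culture was moved from darkness at 37 °C to a moist chamber in dim light at 25 °C. If the mycelium was collected before that move, stage cannot be told apart from temperature, light, moisture and age in comparisons with mycelium. Of 12510 gene models tested, 1882 were higher and 1368 lower in young fruiting bodies (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and of these 594 and 533 changed at least 4-fold. The files give protein IDs and do not pair them with gene names, so the largest changes are given by ID. Model 2997 (330 bp) rose from 3.77 ± 1.72 RPKM in mycelium (SD, n = 3) to 9193 ± 1724 in young fruiting bodies (SD, n = 2), a log2 fold change of 11.26 ± 0.54 (SE, adjusted p = 3.61e-05, edgeR). Model 9817 (345 bp) rose from 0.0885 ± 0.0892 RPKM (SD, n = 3) to 249 ± 17.6 (SD, n = 2; adjusted p = 7.91e-05, edgeR). Only 2 unique reads of model 9817 were counted in the 3 mycelium libraries together, against 4334 in the young fruiting bodies. The ratio of these counts, scaled to TMM-adjusted library sizes, was 3034, with a 95% exact interval of 839 to 25063 that covers counting error only. Model 3027996 (651 bp) fell from 16585 ± 8584 RPKM (SD, n = 3) to 5.59 ± 2.01 (SD, n = 2), a log2 fold change of -11.53 ± 0.99 (SE, adjusted p = 0.000186, edgeR). Model 3027993 (660 bp) fell from 23493 ± 12082 RPKM (SD, n = 3) to 10.0 ± 1.04 (SD, n = 2), a log2 fold change of -11.20 ± 1.32 (SE, adjusted p = 0.000719, edgeR). As the naming rule required, each of the 4 models was higher, or lower, in every young fruiting body library than in every mycelium library.

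Few models went from near silence to abundance: 23 called models were below 1 RPKM in every mycelium library and at or above 10 RPKM in both young fruiting body libraries, and 2 showed the opposite. The number of calls moved by over 1.5 times with single libraries. It was 5141 without fruiting body replicate 3, which enters this comparison through the filter, the scaling and the shared estimate of the spread, and 1052 and 1615 without young fruiting body replicates 1 and 2. It was 2133, 1907 and 2021 without mycelium replicates 1, 2 and 3. Models changed at least 4-fold numbered 475 higher and 223 lower without young fruiting body replicate 1, and 592 higher and 329 lower without replicate 2. The excess of rises over falls was absent in some alternatives. Without fruiting body replicate 3, 612 were higher and 619 lower, with DESeq2 597 and 607, and with only the 2 stages compared 604 and 616. In others it remained, with 577 and 545 under limma-voom, 515 and 446 with the replicate block, and 584 and 543 with the flowcell covariate. Without mycelium replicates 1, 2 and 3 the numbers were 550 and 470, 513 and 440, and 558 and 444.

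**Figure D2:**
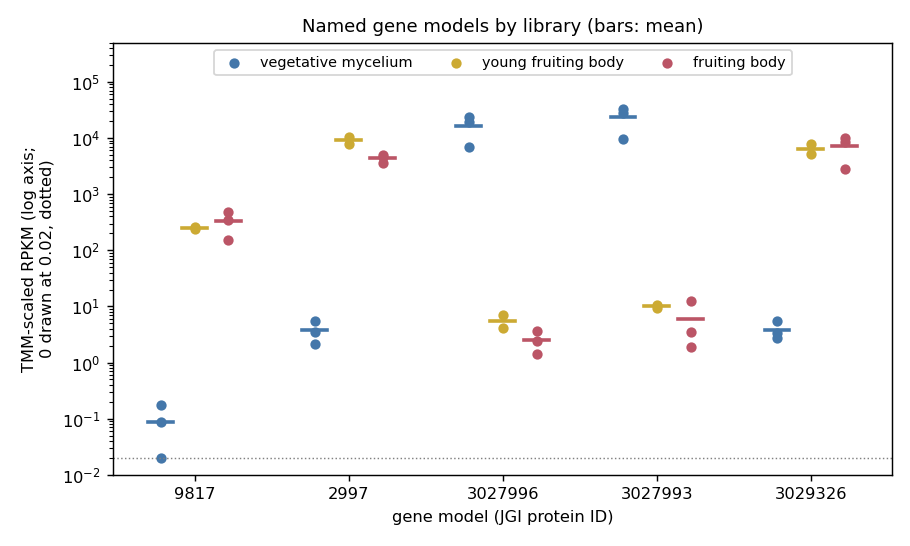
RPKM of the 5 gene models with the largest rises and falls against mycelium, on a log axis, with 1 point per library and a bar at the mean of each stage (mycelium n = 3, young fruiting body n = 2, fruiting body n = 3). Models 9817, 2997 and 3029326 are higher in every fruiting library than in every mycelium library, and models 3027996 and 3027993 are lower. The naming rule required this in the comparison that named each model.

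The whole course from mycelium to the spore-releasing fruiting body was addressed by comparing fruiting bodies with mycelium. In fruiting bodies 2296 models were higher and 1681 lower (edgeR), of which 584 and 438 changed at least 4-fold. Model 3029326 (339 bp) rose from 3.86 ± 1.41 RPKM (SD, n = 3) to 7105 ± 3819 (SD, n = 3), a log2 fold change of 10.86 ± 0.74 (SE, adjusted p = 7.65e-05, edgeR). It was already at 6473 ± 1741 RPKM (SD, n = 2) in young fruiting bodies. Model 9817 stood at 326 ± 164 RPKM in fruiting bodies (SD, n = 3; adjusted p = 6.79e-05, edgeR), with a ratio of counts to mycelium, scaled in the same way, of 3919 (95% exact interval 1085 to 32371). The largest falls were those of models 3027996, to 2.53 ± 1.14 RPKM (SD, n = 3; log2 fold change -12.67 ± 0.85, SE, adjusted p = 7.65e-05, edgeR), and 3027993, to 6.0 ± 5.83 RPKM (SD, n = 3; log2 fold change -11.93 ± 1.11, SE, adjusted p = 0.000200, edgeR). Model 3027993 stood at 1.86, 3.47 and 12.7 RPKM in fruiting body replicates 1, 2 and 3, and its log2 fold change was -13.08 without replicate 3. As the naming rule required, all 4 were higher, or lower, in each fruiting body library, replicate 3 included, than in every mycelium library.

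Without fruiting body replicate 3 the count of calls rose from 3977 to 6099, with 3020 higher and 3079 lower, so that rises no longer outnumbered falls. The count fell to 2637 and 2548 without fruiting body replicates 1 and 2 and to 2592, 2511 and 2448 without mycelium replicates 1, 2 and 3. Models changed at least 4-fold numbered 674 higher and 772 lower without fruiting body replicate 3, and 552 higher and 277 lower with the flowcell as a covariate. With the flowcell as a covariate 1244 models were called, and 3524 on the flowcell of replicate 2 alone, where the fruiting body has a single library whose spread is assumed to be that of the other stages. The other flowcell held fruiting bodies only, so it gives no comparison of its own. With the covariate, the fitted level of the fruiting body therefore rests on replicate 2 as well.

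Fruiting body and young fruiting body were compared to address the step from initials to spore release. No model was called with all 8 libraries (edgeR, smallest adjusted p = 0.0698). Of the 12510 models tested, 987 had an unadjusted p below 0.05 (edgeR), where a share of about 0.05 would pass if none differed. Over the alternatives that number ranged from 464 with the flowcell as a covariate to 1499 without fruiting body replicate 3. Other tools called 242 models (DESeq2), 1 (limma-voom) and 0 (limma-trend on the deposited log2 RPKM). Without fruiting body replicate 3, 45 models were higher and 36 lower in fruiting bodies, of which 23 and 12 changed at least 4-fold. In simulated data for this setting 15 of 123 calls were false. These calls may therefore hold more false ones than their adjusted p implies.

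The models named here for this step were taken without replicate 3, a choice made after that library had been seen to stand apart. Model 2984155 (744 bp) stood at 5.13 ± 0.169 RPKM in young fruiting bodies (SD, n = 2) and 163 ± 111 in fruiting body replicates 1 and 2 (SD, n = 2), a log2 fold change of 4.99 ± 0.51 (SE, adjusted p = 0.00995, edgeR). In replicate 3, scaled in the fit of all 8 libraries, it was at 10.6 RPKM, and with all 8 libraries its adjusted p was 0.298. Model 2989108 (460 bp) stood at 12.2 ± 0.714 RPKM and 132 ± 70.2 in the same libraries (SD, n = 2 each; log2 fold change 3.44 ± 0.43, SE, adjusted p = 0.0170, edgeR), and at 13.0 RPKM in replicate 3. In mycelium these models stood at 114 ± 25.8 and 142 ± 47.3 RPKM (SD, n = 3). Model 2975320 (752 bp) went from 391 ± 103 to 39.1 ± 13.1 RPKM (SD, n = 2 each; log2 fold change -3.32 ± 0.31, SE, adjusted p = 0.00448, edgeR), with 8.46 ± 1.12 RPKM in mycelium (SD, n = 3) and 174 RPKM in replicate 3. Model 2909539 (951 bp) went from 26.6 ± 2.69 to 2.57 ± 1.74 RPKM (SD, n = 2 each; log2 fold change -3.33 ± 0.46, SE, adjusted p = 0.0282, edgeR), and replicate 3, at 2.87 RPKM, lay with replicates 1 and 2. With all 8 libraries the adjusted p of model 2909539 was 0.0859. Over the other alternatives the adjusted p of these 4 models ranged from 3.24e-10 to 0.9995.

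**Figure D3:**
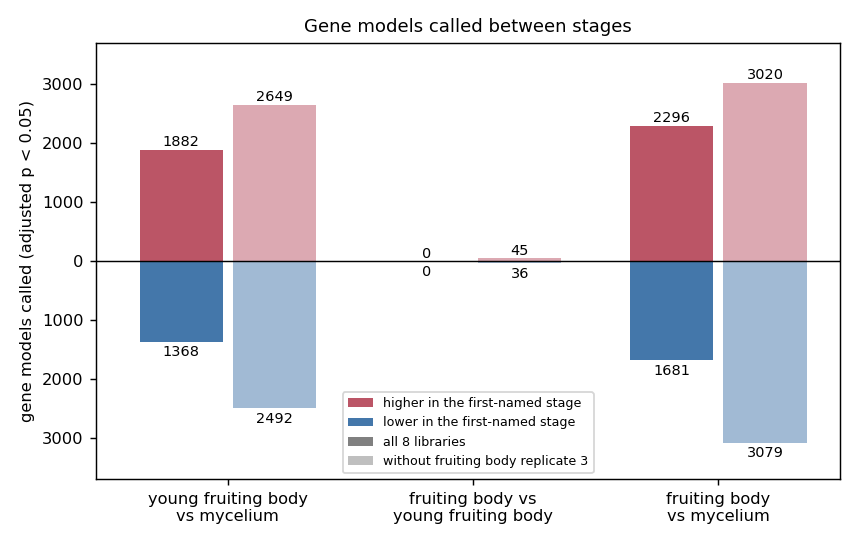
Number of gene models called (adjusted p below 0.05, edgeR) in each comparison of stages, with models higher in the first-named stage above 0 and lower ones below 0, for all 8 libraries (dark) and without fruiting body replicate 3 (light). Against mycelium 3250 and 3977 are called with all libraries, and between fruiting body and young fruiting body 0 with all libraries and 45 higher and 36 lower without replicate 3.

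Across the 3 stages together 3595 of 12510 models differed (28.7%, edgeR quasi-likelihood test on both stage coefficients), of which 1314 changed at least 4-fold between some pair of stages. The count was 5943 without fruiting body replicate 3, 2206 with the flowcell as a covariate, and 2120, 1932 and 2000 without mycelium replicates 1, 2 and 3.

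Calls against mycelium overlapped between the fruiting stages: 1624 models were called higher and 1053 lower in young fruiting bodies and in fruiting bodies alike. The overlap of 2677 models became 4441 (2332 higher and 2109 lower) without fruiting body replicate 3 and 978 (663 and 315) and 1483 (1008 and 475) without young fruiting body replicates 1 and 2. It became 1729, 1576 and 1635 without mycelium replicates 1, 2 and 3, and 1131 with the flowcell as a covariate. Independent lists of these lengths would share 345 and 184 models, and in 20 simulations of unchanged stages, where hardly any model is called in either comparison, the highest overlaps were 1 and 0. Those simulated overlaps therefore do not measure what shared controls add to lists of this length. Across models, which are not independent replicates, the log2 fold changes of both comparisons correlated at r = 0.896, against 0.442 in the simulations, with a covariance of 1.65 against 0.0795, a difference of 1.57. Both comparisons use the same mycelium libraries, and 3 libraries cannot be split into parts of at least 2, so part of the excess of the overlap over independent lists may come from these shared controls. The simulated stages share them too, but each simulated model had the same mean and dispersion in all stages. The difference of covariances may therefore still hold some of that part.

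No model was called higher, or lower, in young fruiting bodies than in both other stages with all 8 libraries (edgeR), where the comparison with fruiting bodies called none. DESeq2 gave 52 higher and 86 lower such models, limma-voom 1 and limma-trend 0. Without fruiting body replicate 3, 19 models peaked in young fruiting bodies and 25 were lowest there. Independent lists would share 7.64 and 8.99, but both comparisons use the same young fruiting body libraries. Simulations of unchanged stages with those 7 libraries gave at most 0 and 2, and since they call hardly any model they do not measure what the shared libraries add.

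A set of 604 models, called at least 4-fold higher in young fruiting bodies than in mycelium in a fit of those 5 libraries alone, took 0.820 ± 0.0372% of unique reads in mycelium (SD, n = 3) and 17.5 ± 3.85% in young fruiting bodies (SD, n = 2), the libraries used to choose it. In the fruiting bodies, which had no part in the choice, it took 15.9 ± 6.40% (SD, n = 3), with 21.2, 17.6 and 8.76% in replicates 1, 2 and 3. The 616 models at least 4-fold lower took 23.6 ± 4.06% in mycelium (SD, n = 3) and 1.41 ± 0.238% in young fruiting bodies (SD, n = 2). They took 1.54, 2.13 and 7.75% in fruiting body replicates 1, 2 and 3.

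**Figure D4:**
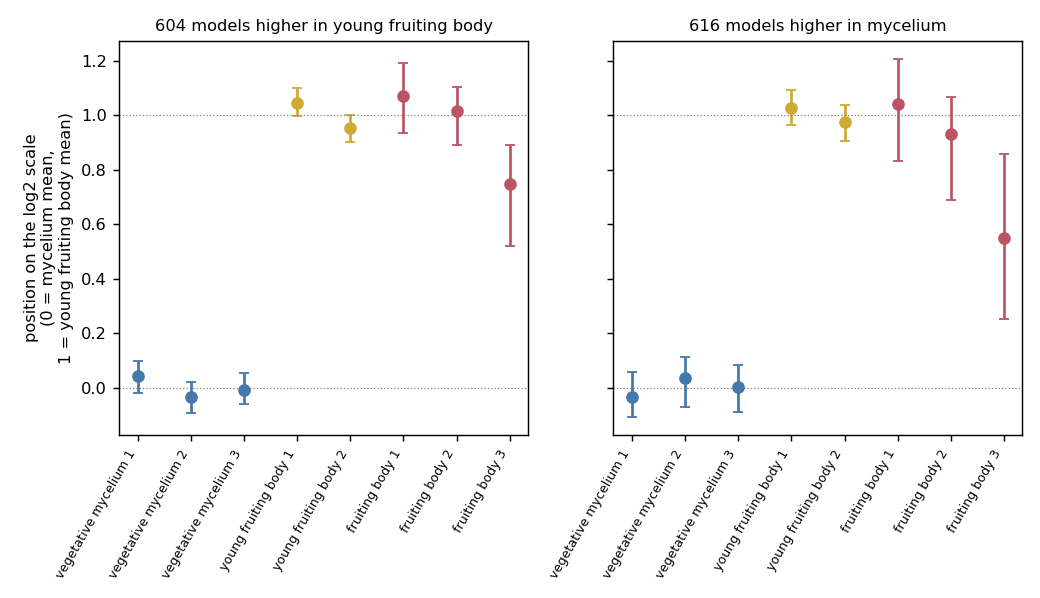
Median (points) and quartiles (bars) of the position of each library between the mycelium mean (0) and the young fruiting body mean (1) of log2 CPM, over 604 models higher (left) and 616 lower (right) in young fruiting bodies than in mycelium. Fruiting body replicates 1 and 2 have medians from 0.929 to 1.07 and replicate 3 has 0.748 and 0.548.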

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

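A signal lay in reads that the comparisons of unique reads do not use. Of 698 gene models with 0 unique reads in every library, 61 had more than 3 total gene reads in at least 1 library, which is more than a count of 0 allows. The highest had 13250 total reads in 1 library, and together these models took 177782 reads over the 8 libraries, or 0.0981% of all gene reads. Scaled to library size, they took 749, 794 and 838 CPM of all gene reads in mycelium replicates 1, 2 and 3, 1293 and 1013 in the young fruiting bodies, and 1164, 992 and 1044 in fruiting body replicates 1, 2 and 3. The difference between stages was not tested, and no biological explanation was tested. These models stay outside every count of calls from unique reads.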

How the results depend on the processing

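Counts in this part that come from limma-trend, and those of models peaking in young fruiting bodies under limma-voom, upper-quartile factors, no filter, the RPKM filter, total gene reads or the shared flowcell alone, were chosen after seeing the data. Of 53 counts of calls under alternatives other than leaving out a single library, 41 stayed within 1.5 times the value with all 8 libraries. Where that value was 0, only a count of 0 was taken as within it. Models peaking or lowest in young fruiting bodies must number 0 where fruiting body against young fruiting body has 0 calls. Those counts are therefore not separate signs of stability. In fruiting body against young fruiting body, 0 became 242 with DESeq2, 64 on the shared flowcell alone, and 1 each with limma-voom, upper-quartile factors and the flowcell as a covariate. The flowcell covariate gave 1244 calls in fruiting body against mycelium and 2206 across the 3 stages. Models peaking or lowest in young fruiting bodies went from 0 to 138 with DESeq2, 47 on the shared flowcell alone, and 1 each with limma-voom, upper-quartile factors and the flowcell covariate. With the flowcell covariate, the fitted level of the fruiting body rests on replicate 2, as the other flowcell held fruiting bodies only. Counts with that covariate therefore do not measure an effect of flowcell. What caused the other shifts was not tested.

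With each library left out in turn, calls ranged from 1052 to 5141 in young fruiting body against mycelium, 0 to 81 in fruiting body against young fruiting body, 2448 to 6099 in fruiting body against mycelium, 1932 to 5943 across the 3 stages and 0 to 44 for models peaking or lowest in young fruiting bodies. Every highest value was the one without fruiting body replicate 3. Of the calls with all libraries, 1023 to 3250 were kept in the same direction in young fruiting body against mycelium and 2432 to 3888 in fruiting body against mycelium, and 0 changed sign. Where 1 young fruiting body library was left, it was assumed to vary like the other stages. The named models against mycelium kept direction and call in all 76 alternative values of each comparison. Those of fruiting body against young fruiting body kept both in 8 of 76 and lost the call in 68, and 0 reversed.

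No pairing of samples by replicate number was seen, but it cannot be excluded. Deviations of same-numbered libraries from their stage means correlated between -0.28 and 0.20, and those of differently numbered libraries between -0.25 and 0.32. The young fruiting body deviations mirror each other, so their values are not independent. With the replicate block 2218, 0 and 3492 models were called in young fruiting body against mycelium, fruiting body against young fruiting body and fruiting body against mycelium, 2763 across the stages, and 0 peaked in young fruiting bodies. The alternatives planned for gene lists were not run, since no list could be applied. Depth limited low models: a 0 in mycelium replicate 1 allows 0.176 CPM.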

Other observations

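The tests of fruiting body replicate 3 in this part were chosen after that library had been seen to stand apart. The tests of the splits, of short models and of models with shared reads were chosen before their results were seen, except the margin of 1 SE around the bound for the last 2 and the other minimums of shared reads.

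Beyond the stage comparisons, short gene models changed more often than others. Of the 1252 tested models of at most 537 bp, the shortest 10%, 11.6% were called at least 4-fold changed between young fruiting bodies and mycelium, 71 higher and 74 lower. Among 10000 random lists matched on mean log2 CPM the median was 8.07%, and the central 95% of lists ended at 9.50%. The share lay above that bound, as the hypothesis that short models change more often predicted. The lists here and below draw models singly, so the bound does not allow for models that vary together. The share was computed in the main fit only. Whether they take a larger part in the start of fruiting was not tested. No name or sequence was used here to say what they encode, and errors in short model predictions stay open.

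The hypothesis that models sharing reads with a near-identical copy change more often did not meet its prediction, though only by a narrow margin. Of 469 models with at least 5% of their reads not unique, 9.81% were called at least 4-fold changed (36 higher and 10 lower), against a median of 7.68% in matched random lists, the central 95% of which ended at 10.0%. By the rule fixed beforehand, a share at or below that bound counts against the hypothesis. The share lies within its binomial SE of 1.37 percentage points of the bound. With that margin, which was added after the result was seen, the hypothesis is left undecided. The minimum of 5% was a free choice: at 1, 20 and 50% the shares were 9.44, 10.1 and 15.4%, and the central 95% of lists ended at 9.77, 11.2 and 13.5%. The share at 50% rests on 52 models, of which 8 were called.

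Fruiting body replicate 3 had 217 models over 2-fold outside the range of all other libraries, against 8 to 41 in each of the others. The values argue against mycelium of the sampled composition mixed into it as the only source of this difference. Over 125 models at least 16-fold higher in mycelium than in young fruiting bodies, its ratio to the mycelium mean was uneven. The SD was 2.54 times that of the most variable mycelium library, and 28 models were under 5% of the mycelium level and 35 at 50% or more. The best mixture of the mycelium mean with the mean of fruiting body replicates 1 and 2 (13% mycelium) gave 0.495 times. That mixture holds no variation between libraries, so a real mixed library would vary more. Variation of the fruiting body tissue of replicate 3 in these models was not allowed for. Flowcell alone does not account for the distance of replicate 3, as replicates 1 and 2 from different flowcells correlated 0.0651 above its best value with either. Its best correlation with mycelium lay 0.105 below the lowest within mycelium, which argues against a mycelium library under the wrong label. With young fruiting bodies it lay 0.0644 below the value within that stage, about as far as from its own stage. Correlations therefore cannot tell a fruiting body label from a young fruiting body label for this library. A different time of harvest, tissue of another age or a handling difference could lie behind the distance of replicate 3 and stays untested.

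The calls between fruiting body and mycelium were set against other splits of these 6 libraries into 3 and 3. Of 10 splits, 1, the real one, gave as many calls: 3401 in the fit of these libraries alone, and the highest of the others was 0. With 10 splits the share cannot go below 0.05.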
